A study of Homo sapiens with 26 samples.

How the data were processed

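Expression was measured by RNA sequencing of poly(A) RNA from LoVo cells, a human colorectal cancer line, in 26 libraries. Wild-type LoVo cells and 2 lines derived from them, with the PIK3CA mutations E545K and H1047R introduced by lentivirus per the series description, were used. That description names clones for the palbociclib experiment alone, so whether the conditioned-medium libraries and the second table come from the same clones is not stated. PIK3CA encodes the catalytic subunit of a lipid kinase. The first table holds 18 libraries in 9 groups of 2: each of the 3 genotypes in DMSO, in 0.5 µM palbociclib, and in conditioned medium of senescent cells. The second table holds 8 libraries in 4 groups of 2: both mutant lines in 0.5 µM palbociclib, alone or with 4 µM erlotinib. Cells grew in DMEM with 10% fetal bovine serum, per the labels' protocols. Those protocols give 72 hours for palbociclib and DMSO and 48 hours for palbociclib with erlotinib. They also state that control cells were collected at 48 hours, without saying which libraries this covers. The hours in conditioned medium, the cells the medium came from, and the hours of palbociclib alone in the second table are not stated there.

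The deposited values are FPKM, fragments scaled to transcript length and to the mapped fragments of the library, per the file headers, with 1 column per library and 2 decimals. HISAT2 2.1.0, Bowtie2 2.3.4.3, RSEM 1.3.1 and DESeq2 1.4.5 are named for the build GRCh38 (hg38), per the submitters' processing notes, which do not say what each did. No normalization between libraries is stated per the labels. Genes carry NCBI Gene IDs and symbols in the tables, which list 18165 and 17734 genes. FPKM sums per library ran from 441643 to 524290. Read depth is unknown, since the tables hold no counts, so no counting interval or detection floor is given. Steps between the low values of 181 genes with at least 1 zero gave a coarse relative depth of 0.86 to 1.00 in the first table, and those of 460 genes gave 1.00 throughout in the second. In these genes 77.1% and 69.4% of low values lay within 0.15 of a whole multiple of the smallest step. The 2-decimal rounding limits this measure.

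Everything below was computed from the FPKM values with R 4.3.3 and limma 3.58.1, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Values were transformed to log2(FPKM + 1). Genes with FPKM of at least 1 in at least 2 libraries of a table were tested, which left 12607 genes in the first table and 12463 in the second. The 2 tables were fitted apart, as they are separate files and each comparison lies within a table. Each fit had 1 coefficient per group and no other term, with empirical Bayes moderation and an intensity trend. The spread of a gene was pooled over all groups of its table. Residual SD on the log2 scale was 0.119 in H1047R DMSO and 0.159 in H1047R palbociclib against 0.067 to 0.081 in the other groups of the first table. In the second it was 0.117 in H1047R palbociclib against 0.062 to 0.068. Residual degrees of freedom were 9 and 4, and the prior added 5.58 and 4.30. P-values, for tests in both directions, were adjusted per comparison with the Benjamini-Hochberg method and called below 0.05. All p-values of single genes in the text are these limma values. The 15 comparisons, the gene lists, the rule for named genes, 7 alternatives and the use of an estimated correlation were fixed before the data were examined. Comparisons of responses between lines were tested as contrasts of contrasts. Replicate numbers were not taken to pair the samples, so the main model has no replicate term. Deviations of replicate 1 from its group mean were correlated across genes between groups. Over 36 combinations of groups in the first table this ran from -0.56 to 0.55 (median 0.07). It was over 0.1 in 15 and under -0.1 in 6, so structure shared by some libraries is not excluded. In the second table it ran from -0.10 to 0.03.

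The median log2 change of all genes lay more than 0.1 from 0 in 7 comparisons, and this depends on the scaling between libraries. It was 0.252 for E545K and 0.261 for H1047R against wild type in DMSO. It was 0.138 for palbociclib in wild type and 0.292 for conditioned medium in wild type. For the difference in response against wild type it was -0.166 for palbociclib in H1047R, and -0.229 and -0.274 for conditioned medium in E545K and H1047R. In these 7 comparisons log2 changes of genes are given relative to that median and called relative log2 changes, while the test itself is of the change from 0. Medians of gene lists are given relative to all genes in every comparison.

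The 19 fixed lists of genes, tested with camera, were: DNA replication and E2F targets, G2/M and mitosis, p53 targets, secreted factors of senescent cells, EGFR family ligands and receptors, ERK pathway output, FOXO targets, sterol and fatty acid synthesis, type I interferon response, antigen presentation, NF-kB targets, Wnt targets and intestinal stem cell markers, enterocyte and goblet cell differentiation, mesenchymal and matrix genes, lysosome and autophagy, hypoxia and glycolysis, ATF4 and unfolded protein response, ribosome biogenesis, and markers of non-epithelial cells. They were written from general knowledge and share some members. Camera used a preset correlation of 0.01, and p-values were adjusted over all lists and comparisons of a table. Camera with an estimated correlation was run beside it. That version also takes the residual degrees of freedom of the fit, 9 and 4, so it can lose a call at a low correlation. Interferon genes under palbociclib in H1047R had an estimated correlation of 0.018. Their unadjusted camera p was 1.31e-26 with the preset and 4.39e-06 with the estimated correlation. Lists with fewer than 5 measured members were not tested, which left out the non-epithelial markers with 3 measured genes in the first table and 2 in the second. Members past the threshold were counted with the p-value adjusted over all genes, and also adjusted over the list alone.

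Genes are named by a fixed rule. PIK3CA is always named. Per comparison the rule allows up to 6 genes with the largest rise and 6 with the largest fall, at an adjusted p below 0.05. Their mean was at least 5 FPKM in the higher group, their libraries did not overlap between the groups, and their symbol is no clone name. Up to 4 in each direction are allowed for differences in response. From each list, up to 4 called members with the largest change are allowed, with a set of fixed markers such as MKI67, CDKN1A and CXCL8. Results of a few genes that the rule allows are not reported. Genes whose reads near-identical copies share are uncertain, since how the submitters assigned such reads is not stated. Among the named genes these are ALPG, the HLA class II genes, CXCL1, CXCL2 and CXCL3, CEACAM5 and CEACAM6, and the MAGEA and hemoglobin genes. Strand use in counting is not stated either, so antisense transcripts cannot be told apart from their partners. Coordinates come from a RefSeq annotation of GRCh38.p14, matched on NCBI Gene ID.

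Overlaps between comparisons were set against the number expected from independent lists. Pairs that share control libraries were set against 20 simulated draws with unchanged groups. Length and GC content of transcripts came from GENCODE 29 and covered 99.3% of tested genes in each table. The alternatives set beforehand were a pseudocount of 0.1, no filter, rescaling each library to a sum of 1000000 (TPM scale), quantile normalization, a fit of only the libraries of the groups compared, replicate number as a block, and leaving out each library in turn. Median-centring and removal of a length and GC trend, with splines of 4 degrees of freedom each, were added after the data were seen.

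The procedure was also tested on simulated data, drawn from the means and spread of the tested genes; this test was written after the model had first been run on the real values. For palbociclib against DMSO in wild type, 12262 simulated genes were run with 50 genes changed at each fold size. Of these, 4 were recovered at 1.2-fold, 37 at 1.5-fold, 47 at 2-fold and 50 at 4-fold, with 6 calls among 12062 unchanged genes. For added erlotinib in E545K, 12269 genes were run, and 4, 38, 40 and 48 of 50 were recovered at the same sizes, with 7 calls among 12069 unchanged genes. A shift of 0.5 in the mitosis list passed in both simulations, and 0 of 17 unchanged lists did. Genes were drawn independently, with 1 spread per gene for all groups. Correlation within lists and the larger spread of H1047R groups were thus not simulated. In the first table the estimated correlation was 0.137 for mitosis and 0.597 for hypoxia genes, so false calls of correlated lists were not tested. A test on counts was not run.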

Results

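Gene expression was measured in 26 RNA sequencing libraries of LoVo colorectal cancer cells, 2 per group, in wild-type cells and in the PIK3CA mutant lines E545K and H1047R. The series asks how these mutations change the response to palbociclib, an inhibitor of the kinases CDK4 and CDK6 used here to induce senescence. It also asks what medium conditioned by senescent cells does, and what erlotinib, an inhibitor of the EGF receptor, adds in the mutant lines. Total read counts are unknown, because the values are FPKM. From 11453 to 12157 genes reached at least 1 FPKM per library. Replicates correlated across genes at 0.9867 to 0.9974 in the first table and at 0.9904 to 0.9973 in the second, with H1047R in palbociclib lowest in each. Ribosomal protein genes held 17.5% to 27.6% of the FPKM sum. Group values below are mean FPKM ± SD with n = 2, and SE is the standard error of a log2 change.

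**Figure D1:**
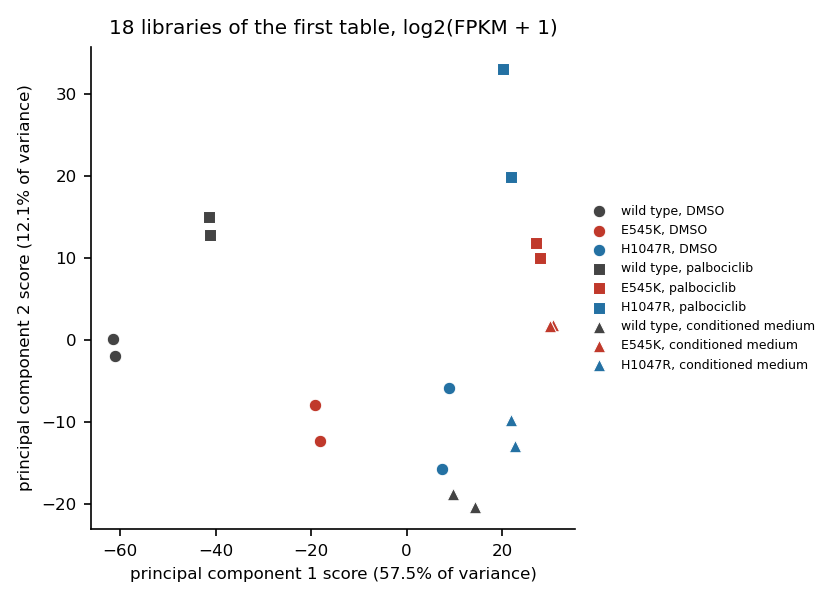
First 2 principal components of log2(FPKM + 1) in the 18 libraries of the first table, each point 1 library, axes in component scores. Component 1 held 57.5% and component 2 held 12.1% of the variance, and wild-type DMSO, wild-type palbociclib and E545K DMSO libraries had negative scores on component 1.

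PIK3CA (chromosome 3, 179148126 to 179240093 in GRCh38.p14) stood at 5.40 ± 0.03 FPKM in wild-type, 7.79 ± 0.59 in E545K and 6.78 ± 0.59 in H1047R cells in DMSO. The relative log2 change was 0.20 in E545K (SE 0.11, adjusted p 0.00323) and 0.02 in H1047R (SE 0.11, adjusted p 0.042). After quantile normalization the H1047R log2 change became -0.13. The H1047R call was also lost with no filter on low values (adjusted p 0.0657), with only the groups compared in the fit (0.0537), without replicate 1 or 2 of wild-type DMSO (0.121 and 0.111) and without H1047R DMSO replicate 2 (0.22), and its alternatives ranged from 0.00294 to 0.556. The E545K call was lost after quantile normalization (0.382) and median-centring (0.178), in a range from 9.56e-06 to 0.382. Under palbociclib PIK3CA stood at 6.96 ± 0.39, 10.16 ± 0.33 and 5.17 ± 1.11 in wild type, E545K and H1047R, and in conditioned medium at 6.06 ± 0.19, 15.70 ± 0.78 and 6.27 ± 0.74. In the second table it stood at 11.88 ± 0.31 in E545K and 7.30 ± 0.43 in H1047R under palbociclib, and at 12.38 ± 0.50 and 7.42 ± 0.53 with erlotinib. These values do not separate mutant from wild-type PIK3CA transcripts, so the mutant transcript itself was not measured.

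The mutant lines were first compared with wild type in DMSO, which asks what the mutations change before treatment. E545K cells had more MSLN, FAM151A, ANXA8, CRIP1, LRRN4 and PTN than wild type, and less HBE1, CCL26, OR51B5, MAGEA6, FGFBP1 and S100P. MSLN stood at 12.5 ± 0.16 against 0.69 ± 0.07 FPKM (relative log2 change 2.75, SE 0.14, adjusted p 1.23e-09). HBE1, an embryonic globin gene, stood at 4.99 ± 0.61 against 148 ± 6.75 (-4.89, SE 0.14, adjusted p 1.55e-11). EGFR rose to 74.8 ± 2.28 from 24.0 ± 2.22 FPKM (1.35, SE 0.15), while its ligand gene AREG was lower (-1.48, SE 0.10) and CXCL8 was lower (-2.44, SE 0.18). In the list of DNA replication and E2F targets 44 of 49 genes were higher and 1 lower (44 and 1 adjusted over the list alone), and camera gave an adjusted p of 1.11e-07. Among them BRCA1 stood at 5.7 ± 0.26 against 1.3 ± 0.29 FPKM, and CCNE2 changed by 1.07. Sterol and fatty acid synthesis was lower in 21 of 30 genes and higher in 3 (21 and 3 adjusted over the list alone), with a median of -1.18 and an adjusted p of 1.44e-21. INSIG1, SCD and HMGCS1 changed by -2.39, -2.26 and -2.10. The list of ATF4 and unfolded protein response was lower in 14 of 28 genes (15 adjusted over the list alone) and higher in 3, with ATF3 at -1.42 and DDIT3 at -1.36, and an adjusted p of 5.3e-09. The stem cell marker LGR5 was higher (1.17, SE 0.16), but Wnt targets and intestinal stem cell markers as a list did not pass (9 of 17 higher, 2 lower, adjusted over the list alone 9 and 2, adjusted p 0.599), and their counts became 5 and 4 after quantile normalization and 6 and 5 after median-centring. For type I interferon genes the counts changed direction with scaling, from 15 higher and 11 lower of 38 to 6 and 18 after quantile normalization. Their median relative to all genes was -0.15 while their mean log2 change was 0.02, and camera called them lower (adjusted p 0.0322), a call lost with an estimated correlation (0.145), no filter on low values (0.199) and median-centring (0.0605), in a range from 0.0181 to 0.199. Of 12607 genes, 6096 were higher and 1311 lower, 82.3% higher. After quantile normalization 3168 were higher and 2811 lower, and after median-centring 43.8% were higher.

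H1047R cells shared much of this difference from wild type, and their p53 targets were lower as a list. Much of it also appeared within wild type, between conditioned medium and DMSO. Mean profiles of wild type in conditioned medium correlated across genes at 0.986 with H1047R in DMSO and at 0.938 with wild type in DMSO. On component 1 wild-type DMSO libraries scored -61.1 and -61.5, wild type in conditioned medium 14.3 and 9.7, and H1047R DMSO 8.8 and 7.5. PPP1R10, GDF15 and S100P stood at 30.1, 66.0 and 11.6 FPKM in H1047R DMSO and at 32.5, 68.2 and 9.84 in wild type in conditioned medium. OR51B5 and MAGEA6 did not follow, at 0.085 and 0.07 FPKM in H1047R DMSO and 11.8 and 20.4 in wild type in conditioned medium. In H1047R against wild type in DMSO, FAM151A, PPP1R10, LGR5 and HPS6 were among the genes raised most. HBE1, GDF15, S100P, OR51B5, MAGEA6 and PCK1 were among those lowered most. LGR5 stood at 41.6 ± 0.87 against 4.54 ± 0.08 FPKM (relative log2 change 2.68, SE 0.16, adjusted p 1.3e-09). GDF15 stood at 66.0 ± 2.45 against 910 ± 27.2 (-4.03, SE 0.13, adjusted p 3.36e-11). p53 targets were lower in 19 of 28 genes and higher in 4 (19 and 4 adjusted over the list alone), with a median of -0.87 and an adjusted p of 1.62e-10, among them CDKN1A (-2.27) and PLK3 (-2.68). The ERK pathway output list was lower in 15 of 25 and higher in 4 (15 and 4 adjusted over the list alone; adjusted p 5.9e-07), with DUSP5 at -2.86. Sterol genes were lower in 20 of 30 and higher in 3 (20 and 4 adjusted over the list alone; adjusted p 2.37e-12), with INSIG1 at -2.68 and HMGCS1 at -2.34. ATF4 genes were lower in 22 of 28 and higher in 1, also adjusted over the list alone (adjusted p 7.65e-13), with CTH at -2.36 and DDIT4 at -1.89. Replication genes were higher in 42 of 49 and lower in 2 (43 and 3 adjusted over the list alone), BRCA1 by 1.76, with an adjusted p of 3.22e-06 that became 0.0667 with an estimated correlation. EGFR rose by 0.76 (SE 0.15) and AREG fell by 2.20 (SE 0.10), both relative to the median. Of 3 measured markers of non-epithelial cells 2 were higher in H1047R, also adjusted over the list alone, COL3A1 by 0.72 (SE 0.09), and 0 were called in E545K. After quantile normalization or median-centring 1 was higher in H1047R and 1 lower in E545K. Of the 216 list tests of the first table, 130 passed camera with the preset correlation and 62 with both. In total 6286 genes were higher and 2206 lower, 74.0% higher, which became 51.5% after quantile normalization and 41.6% after median-centring. Both mutants were higher than wild type in 4751 genes and lower in 964, with a correlation of changes across genes of 0.73. The wild-type libraries are shared by both comparisons. In simulated unchanged groups such sharing gave a correlation of 0.50 and a covariance of 0.0075, against an observed covariance of 0.205. Because each mutation is present in 1 line, line and mutation cannot be separated here, nor can either be separated from what sets the wild-type DMSO libraries apart from wild type in conditioned medium.

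Palbociclib against DMSO asks what the CDK4/6 inhibitor changes in each genotype. In wild-type cells it raised interferon genes and lowered mitotic genes, and it raised antigen presentation genes with the preset but not the estimated correlation of camera. CD74, the invariant chain of HLA class II (chromosome 5, 150401639 to 150412910 in GRCh38.p14), stood at 137 ± 3.57 against 27.8 ± 0.79 FPKM (relative log2 change 2.12, SE 0.14, adjusted p 8.88e-08). CFB, MMP7, PI3, CEACAM5 and CEACAM6 rose by 2.08, 1.90, 1.82, 1.77 and 1.74. GDF15 was lower at 338 ± 14.3 against 910 ± 27.2 FPKM (-1.56, SE 0.13), as were ALPG (-1.48), TNFRSF10D (-1.46), ARTN (-1.33) and CXCL8 (-1.24). G2/M and mitosis genes were lower in 37 of 42 and higher in 0, also adjusted over the list alone, with a median of -0.70 and an adjusted p of 3.98e-33. MKI67 stood at 24.9 ± 1.02 against 49.0 ± 4.58 FPKM (-1.09, SE 0.19), and TOP2A, UBE2C and LMNB1 changed by -0.84, -1.12 and -0.67. Replication genes were lower in 16 of 49 and higher in 3, also adjusted over the list alone (adjusted p 5.3e-09), with CDT1 at -1.02 and RRM2 at -0.77 but CCNE1 at 0.45. CCND1 rose by 0.32 (SE 0.06). Interferon genes were higher in 35 of 38 and lower in 0, also adjusted over the list alone (median 0.71, adjusted p 2.37e-17), with IFI6 at 1.70 and ISG15 at 0.95. Antigen presentation was higher in 20 of 21 (21 adjusted over the list alone), HLA-DRB1 by 1.65, with an adjusted p of 4.44e-12 that became 0.0743 with an estimated correlation. p53 targets were lower in 12 of 28 and higher in 2 (15 and 2 adjusted over the list alone; adjusted p 8.81e-08). CDKN1A was lower (-0.70, SE 0.11) and TP53I3 higher (0.87, SE 0.13). Sterol genes were lower in 19 of 30 (20 adjusted over the list alone; adjusted p 1e-17), INSIG1 by -1.16 and SCD by -1.11. Secreted factors of senescent cells did not pass, with 13 of 48 higher and 11 lower (15 and 12 adjusted over the list alone, adjusted p 0.154), a balance that turned to 10 and 14 after quantile normalization. In all, 3434 genes were higher and 853 lower. The share higher, 80.1%, became 50.8% after quantile normalization and 43.5% after median-centring. Leaving out either DMSO or either palbociclib library of wild type gave 2616 to 2725 genes in place of 4287.

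In E545K cells palbociclib raised interferon genes and NF-kB targets. CCL20 stood at 33.5 ± 2.96 against 0.67 ± 0.16 FPKM (log2 change 4.37, SE 0.25, adjusted p 7.72e-09). SAMD9, MX2, CD74, IFI44L and CXCL2 rose by 3.43, 3.31, 3.29, 3.13 and 2.95. ALPG stood at 16.3 ± 0.58 against 277 ± 3.21 (-4.01, SE 0.13, adjusted p 2.36e-11), and GDF15, INSIG1, CDKN1A, SCNN1A and DUSP5 changed by -3.41, -3.40, -2.67, -2.61 and -2.61. Interferon genes were higher in 37 of 38, also adjusted over the list alone (median 1.59, adjusted p 2.62e-21), IFIT1 by 2.60. Antigen presentation was higher in 20 of 21, also adjusted over the list alone (adjusted p 1.13e-08; 0.133 with an estimated correlation). NF-kB targets were higher in 21 of 28 and lower in 1, also adjusted over the list alone (adjusted p 6.97e-07), with CXCL3 at 2.61, BIRC3 at 2.00 and CXCL1 at 1.98. Secreted factors of senescent cells did not pass, with 20 of 48 higher and 18 lower (20 and 19 adjusted over the list alone, adjusted p 0.966), a balance that turned to 20 and 22 after quantile normalization and 18 and 22 after median-centring. Their median relative to all genes was 0.02 and their mean log2 change 0.31, while camera's direction was lower. p53 targets were lower in 22 of 28 and higher in 3, also adjusted over the list alone (median -0.81, adjusted p 1.29e-10). Sterol genes were lower in 19 of 30 and higher in 5, also adjusted over the list alone (adjusted p 1.31e-09). Mitotic genes were lower in 27 of 42 and higher in 1, also adjusted over the list alone, with a median of -0.45 and an adjusted p of 3.94e-09 that became 0.0621 with an estimated correlation. MKI67 stood at 36.3 ± 2.21 against 55.2 ± 9.30 FPKM (-0.58, SE 0.19, adjusted p 0.0204). This call was lost on the TPM scale (0.0577), without E545K DMSO replicate 1 (0.171) and without replicate 1 or 2 of E545K palbociclib (0.108 and 0.0511), in a range from 0.00015 to 0.171. TOP2A changed by -0.65 and KIF2C by -0.87. Replication genes did not pass as a list (13 of 49 higher, 10 lower, also adjusted over the list alone, adjusted p 0.563), a balance that turned to 12 and 13 after quantile normalization and 12 and 14 after median-centring. Ribosome biogenesis was higher in 21 of 24 (21 higher and 1 lower adjusted over the list alone; adjusted p 7.95e-06). CCND1 rose by 0.84 (SE 0.06) and LGR5 by 2.01 (SE 0.16). In all, 4145 genes were higher and 2434 lower, 63.0% higher, which became 49.5% after quantile normalization and 44.0% after median-centring. On component 1 E545K DMSO libraries scored -18.2 and -19.1, on the side of wild-type DMSO, and E545K palbociclib libraries 27.9 and 27.2. The palbociclib change of E545K correlated across genes at 0.64 with conditioned medium against DMSO in wild type. With palbociclib in wild type and H1047R it correlated at 0.53 and 0.52. An effect of palbociclib cannot be separated here from what sets the E545K DMSO libraries apart.

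In H1047R cells palbociclib raised HLA class II and NF-kB genes. CD74 stood at 326 ± 40.2 against 17.4 ± 4.38 FPKM (log2 change 4.17, SE 0.14, adjusted p 7.29e-11). CFB, HLA-DRB1, HLA-DPA1, MMP7 and CEACAM5 rose by 3.59, 3.43, 3.23, 3.10 and 2.04, and B2M by 1.44. ALPG stood at 19.4 ± 3.19 against 144 ± 23.7 (-2.83, SE 0.13, adjusted p 1.62e-09), and AKR1C3, FGFBP1, MYB and METTL7A changed by -1.96, -1.74, -1.59 and -1.55. Antigen presentation was higher in 21 of 21, also adjusted over the list alone (median 1.38, adjusted p 6.5e-24). Interferon genes were higher in 33 of 38 and lower in 1 (35 and 1 adjusted over the list alone; adjusted p 9.45e-25), IFI27 by 2.53 and ISG15 by 2.04. NF-kB targets were higher in 22 of 28 (23 adjusted over the list alone; adjusted p 1.81e-13), and secreted factors of senescent cells in 21 of 48, with 3 lower (21 and 4 adjusted over the list alone; adjusted p 1.36e-05). CCL5, CXCL10, CCL20 and TNF rose by 2.32, 2.16, 2.15 and 1.51. Mitotic genes were lower in 33 of 42 (36 adjusted over the list alone; median -0.41, adjusted p 7.65e-13). MKI67 stood at 24.1 ± 10.6 against 58.4 ± 4.02 FPKM (-1.30, SE 0.19) and TOP2A changed by -1.23. Replication genes were lower in 24 of 49 and higher in 2 (26 and 2 adjusted over the list alone), with an adjusted p of 0.00026 that became 0.135 with an estimated correlation. Lysosome and autophagy genes were higher in 16 of 31 and lower in 1 (17 and 1 adjusted over the list alone; adjusted p 0.00116, 0.133 with an estimated correlation). p53 targets did not pass (6 of 28 higher, 8 lower, also adjusted over the list alone, adjusted p 0.832). CDKN1A did not change detectably (0.06, SE 0.11, adjusted p 0.671), GDF15 fell by 1.01 (SE 0.13) and CCND1 rose by 0.71 (SE 0.06). Enterocyte and goblet cell differentiation (6 of 13 higher, 3 lower, also adjusted over the list alone; adjusted p 0.0458) and mesenchymal and matrix genes (8 of 18 higher, 4 lower, also adjusted over the list alone; adjusted p 0.011) did not pass with an estimated correlation (0.244 and 0.107). The differentiation call was lost in 7 of 13 alternatives, among them those without H1047R DMSO replicate 2 (0.147) and without H1047R palbociclib replicate 1 (0.115), in a range from 0.0123 to 0.244. FOXO targets were lower in 13 of 22 and higher in 2 (14 and 2 adjusted over the list alone; adjusted p 0.00158, 0.204 with an estimated correlation). In all, 2458 genes were higher and 2493 lower, 49.6% higher, which became 52.6% after median-centring and 38.9% on the TPM scale. The total of 4951 became 2732 without H1047R DMSO replicate 2 and 480 with only the groups compared in the fit. H1047R in DMSO and in palbociclib had the largest residual SD (0.119 and 0.159), which the full fit pools with 0.067 to 0.081 in the other groups. Markers of non-epithelial cells, with 3 measured genes, had 0 called in wild type, 1 higher and 1 lower in E545K, and 1 lower in H1047R, also adjusted over the list alone. After quantile normalization or median-centring these became 1 lower in each genotype.

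**Figure D2:**
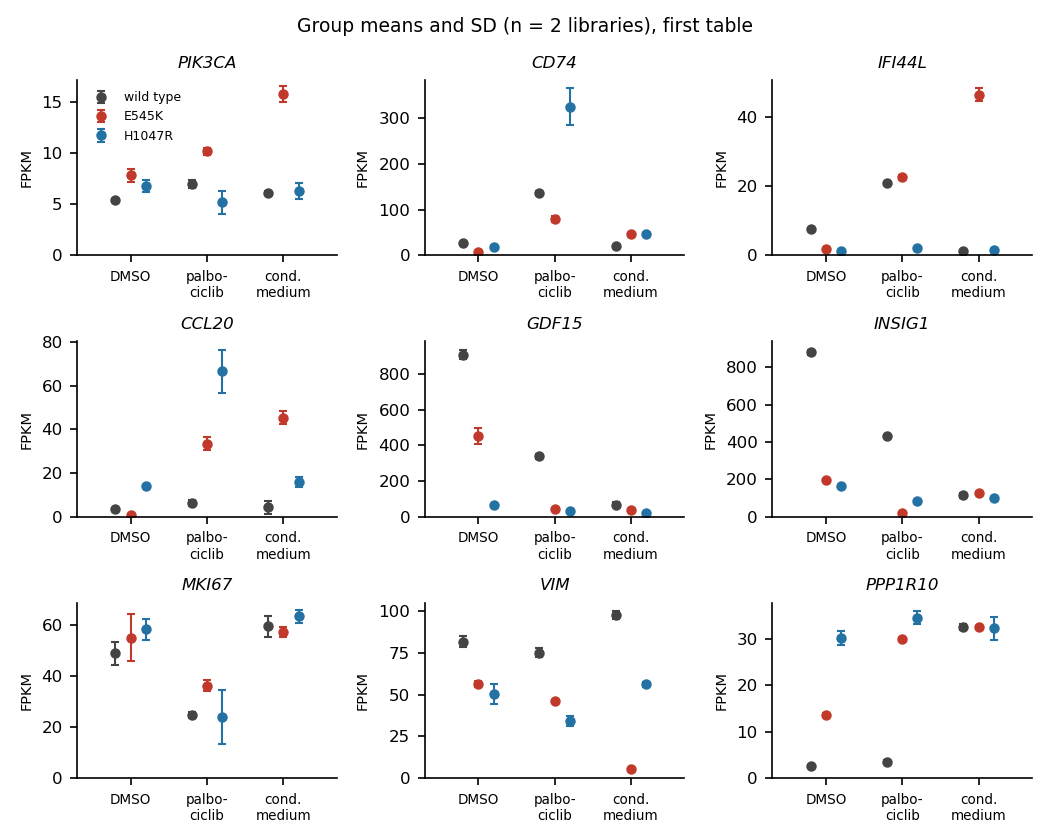
FPKM of 9 named genes in the first table by treatment, each point the mean of 2 libraries of a genotype and each bar its SD. CD74 rose under palbociclib in all 3 genotypes, and CCL20 rose from 0.67 to 33.5 in E545K.

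The palbociclib changes overlapped between genotypes. Wild type and E545K shared 2058 higher and 538 lower genes, where independent lists would share 1129 and 165. Wild type and H1047R shared 1336 and 455 (670 and 169 expected), and E545K and H1047R shared 1565 and 1032 (808 and 481 expected). With only the groups compared in the fit, shared calls fell from 1791 to 396 for wild type and H1047R and from 2597 to 402 for the mutants. Correlations of changes across genes, which are not independent replicates, were 0.53, 0.48 and 0.52. Tested as differences in response, 1377 genes changed more towards higher values in E545K than in wild type and 1857 more towards lower values. For H1047R these numbers were 650 and 2195, a share of 22.8% that became 51.9% after quantile normalization and 64.0% after median-centring. Such differences contain the DMSO libraries, so they are joined to what sets those of wild type and E545K apart. The log2 response of CXCL2 and CCL20 lay higher in E545K than in wild type, by 4.05 (SE 0.17) and 3.69 (SE 0.36). CXCL2 fell in wild type from 10.4 to 4.3 FPKM and rose in E545K from 6.1 to 53.9. ALPG (-2.67, SE 0.18) and KRT14 (-2.47, SE 0.28) differed the other way. The response of IFI27, NOS2 and CXCL8 lay higher in H1047R, with relative differences of 2.50, 2.48 and 2.22, and that of HOXB4 lower (-1.71). CXCL8 fell in wild type from 104.8 to 48.3 FPKM and rose in H1047R from 39.8 to 76.1. HOXB4 rose in wild type from 28.0 to 44.9 and fell in H1047R from 30.3 to 12.8. IFI27 stood at 23.1 in H1047R and 184.8 in wild type in DMSO, and at 139.4 and 212.0 under palbociclib. As lists, interferon genes and NF-kB targets differed towards higher values than in wild type in both mutants, relative to all genes. Without that reference the median log2 change of interferon genes was 0.85 in wild type, 1.67 in E545K and 0.99 in H1047R. Interferon genes differed towards higher values in 28 of 38 in E545K, also adjusted over the list alone (adjusted p 1.74e-19), and in 10 of 38 in H1047R, with 3 towards lower values (14 and 6 adjusted over the list alone; adjusted p 2.72e-07). NF-kB targets did so in 14 of 28 in E545K, with 1 towards lower values (15 and 1 adjusted over the list alone; adjusted p 3.08e-09), and in 16 of 28 in H1047R (20 adjusted over the list alone; adjusted p 3.69e-20). The total of 2845 for H1047R became 1663 and 1291 without replicates 1 and 2 of wild-type DMSO, and 1268 and 1671 without those of wild-type palbociclib. It was 1428 without H1047R DMSO replicate 2, 5562 without H1047R palbociclib replicate 1 and 288 with only the groups compared in the fit.

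**Figure D3:**
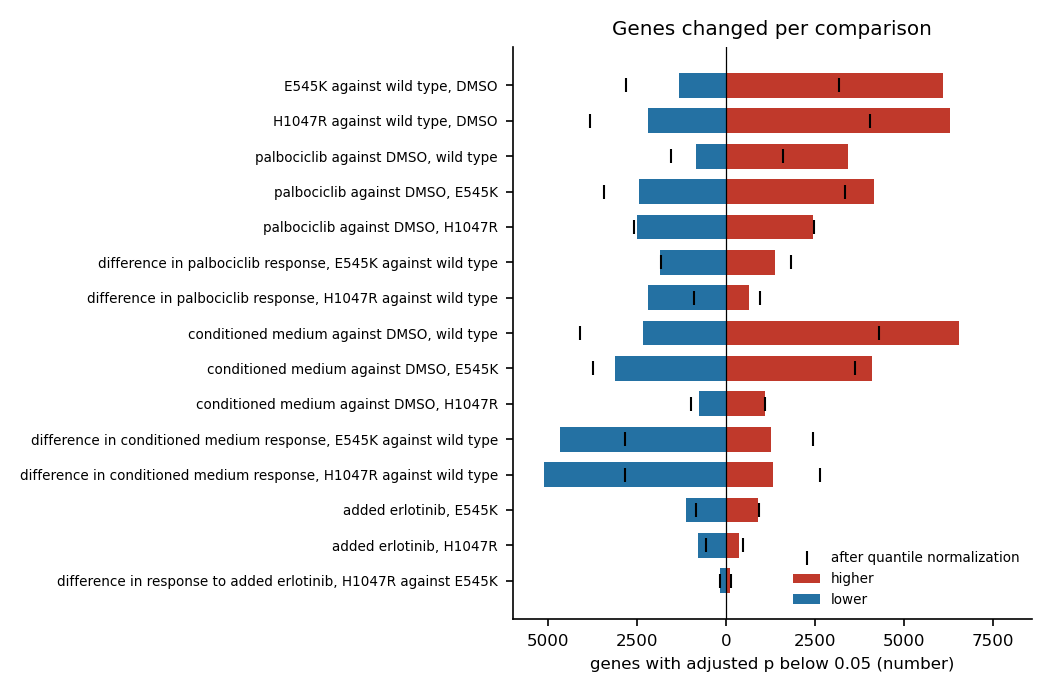
Genes with an adjusted p below 0.05 in each of the 15 comparisons, lower to the left and higher to the right, with black ticks after quantile normalization. In wild type under conditioned medium 6537 genes were higher and 2346 lower, and after quantile normalization 4313 and 4096.

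Conditioned medium of senescent cells was compared with DMSO to ask how cells respond to secreted factors. Medium conditioned by cells without senescence was not compared here, so effects of spent medium and of secreted factors are joined. The series description does not say whether these cells are the same clones as those in DMSO, so a difference between clones is joined to them in the mutant lines. In wild-type cells replication and ribosome biogenesis genes rose, and p53, ATF4 and sterol genes fell. PPP1R10 (chromosome 6, 30600413 to 30617243 in GRCh38.p14) stood at 32.5 ± 0.57 against 2.60 ± 0.28 FPKM (relative log2 change 2.93, SE 0.08, adjusted p 1.74e-12). HPS6, IL37, SEPHS2 and GEMIN4 rose by 2.62, 2.51, 2.42 and 2.38. S100P stood at 9.84 ± 1.10 against 150 ± 3.31 (-4.09, SE 0.16, adjusted p 9.65e-11), and GDF15, DUSP5, CCL26, JUND and GADD45B changed by -4.02, -3.70, -3.52, -3.37 and -3.35. Replication genes were higher in 47 of 49 and lower in 1, also adjusted over the list alone (median 0.71, adjusted p 2.43e-09), BRCA1 by 1.97 and MCM4 by 1.52. Ribosome biogenesis was higher in 23 of 24, also adjusted over the list alone (median 0.89, adjusted p 1.21e-06), POLR1A by 1.56. MYC rose by 1.55 (SE 0.08) and LGR5 by 2.26 (SE 0.16). p53 targets were lower in 20 of 28 and higher in 3, also adjusted over the list alone (adjusted p 8.76e-10), with CDKN1A at -2.48. Sterol genes were lower in 20 of 30 and higher in 4, also adjusted over the list alone (adjusted p 2.37e-12), with INSIG1 at -3.23 and HMGCS1 at -2.79. ATF4 genes were lower in 22 of 28 and higher in 3, also adjusted over the list alone (adjusted p 2.6e-11), with DDIT4 at -3.09. The FOXO target TXNIP was lower at 90.9 ± 12.4 against 449 ± 0.50 FPKM (-2.59, SE 0.09). The interferon list did not pass (22 of 38 higher, 7 lower, also adjusted over the list alone, adjusted p 0.866), with 18 and 11 after quantile normalization and 16 and 13 after median-centring. Of 3 measured markers of non-epithelial cells 2 were higher, also adjusted over the list alone, and 1 after quantile normalization or median-centring. Among them COL3A1 stood at 18.5 ± 1.65 against 3.46 ± 0.15 FPKM (1.83, SE 0.09). The share of genes higher, 73.6%, became 51.3% after quantile normalization and 45.6% after median-centring.

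E545K cells in conditioned medium had higher interferon genes and lower p53 targets than in DMSO. IFI44L stood at 46.6 ± 1.83 against 1.70 ± 0.34 FPKM (log2 change 4.14, SE 0.10, adjusted p 8.62e-13), and IFI6 at 524 ± 40.4 against 32.8 ± 0.21 (3.96, SE 0.12). CCL20, SAMD9, OAS2 and MX1 rose by 4.80, 3.80, 3.58 and 3.45, LCN2 by 2.99 and CD74 by 2.56. VIM stood at 5.42 ± 0.33 against 56.6 ± 1.86 (-3.16, SE 0.08, adjusted p 1.15e-12), and GDF15, AKR1C3, CDKN1A, REEP2 and FN1 changed by -3.63, -3.54, -2.84, -2.69 and -1.53. PIK3CA rose by 0.93 (SE 0.11, adjusted p 7.49e-06). Interferon genes were higher in 35 of 38 and lower in 1, also adjusted over the list alone (median 1.95, adjusted p 3.69e-20). p53 targets were lower in 23 of 28 and higher in 1 (23 and 2 adjusted over the list alone; adjusted p 1.56e-10). Ribosome biogenesis was higher in 22 of 24, also adjusted over the list alone (adjusted p 5.97e-08), POLR1A by 1.39. Replication genes were higher in 26 of 49 and lower in 6, also adjusted over the list alone, MCM3 by 1.24, with an adjusted p of 0.00567 that became 0.233 with an estimated correlation. ERK output was lower in 17 of 25 and higher in 3 (18 and 3 adjusted over the list alone; adjusted p 9.01e-05). In all, 4090 genes were higher and 3133 lower. The share higher, 56.6%, became 49.2% after quantile normalization and 42.9% after median-centring. Of 3 measured markers of non-epithelial cells 2 were lower, also adjusted over the list alone, COL3A1 by -0.86 (SE 0.09), and 1 became higher after quantile normalization.

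H1047R cells changed in fewer genes, 1091 higher and 753 lower. LRRN4 stood at 37.3 ± 1.61 against 7.45 ± 0.51 FPKM (log2 change 2.18, SE 0.09, adjusted p 8.76e-09), and CD74, HLA-DRB1, HLA-DRA and COL16A1 rose by 1.38, 1.36, 1.12 and 1.04. NDRG1 stood at 6.91 ± 0.25 against 25.6 ± 9.87 (-1.70, SE 0.17, adjusted p 5.93e-05), and ANKRD37, GDF15, CLIC3 and DDIT4 changed by -2.03, -1.48, -1.47 and -1.29. Hypoxia and glycolysis genes were lower in 13 of 26 (15 lower and 2 higher adjusted over the list alone), with an adjusted p of 5.29e-09 that became 0.229 with an estimated correlation. The 2 H1047R DMSO libraries differed from each other in members of this list, with ANKRD37 at 11.2 ± 7.4 FPKM there and 1.8 ± 0.8 in conditioned medium. Replication genes were higher in 30 of 49 (37 adjusted over the list alone; adjusted p 1.36e-16), mitotic genes in 20 of 42 (24 adjusted over the list alone; adjusted p 1.63e-11) and ribosome biogenesis in 18 of 24 (20 adjusted over the list alone; adjusted p 1.81e-13). MCM3, PLK1 and MYC rose by 0.54, 0.62 and 0.45. The PLK1 call was lost without H1047R DMSO replicate 2 (adjusted p 0.0529) and with only the groups compared in the fit (0.0628), in a range from 0.000672 to 0.0628. ERK output was lower in 13 of 25 and higher in 3 (14 and 3 adjusted over the list alone; adjusted p 4.18e-06), DUSP5 to 30.2 ± 1.56 from 61.6 ± 5.12 FPKM, and p53 targets in 8 of 28, with 1 higher, also adjusted over the list alone (adjusted p 2.21e-05). TXNIP changed by -0.89. Of 3 measured markers of non-epithelial cells 1 was higher (1 higher and 1 lower adjusted over the list alone). EGFR family ligands and receptors were lower in 4 of 12 (6 adjusted over the list alone; adjusted p 0.011, 0.187 with an estimated correlation). The total of 1844 became 686 without either H1047R conditioned medium library and 1107 without H1047R DMSO replicate 2. It was 605 with only the groups compared in the fit and 3315 after removal of the length and GC trend.

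**Figure D4:**
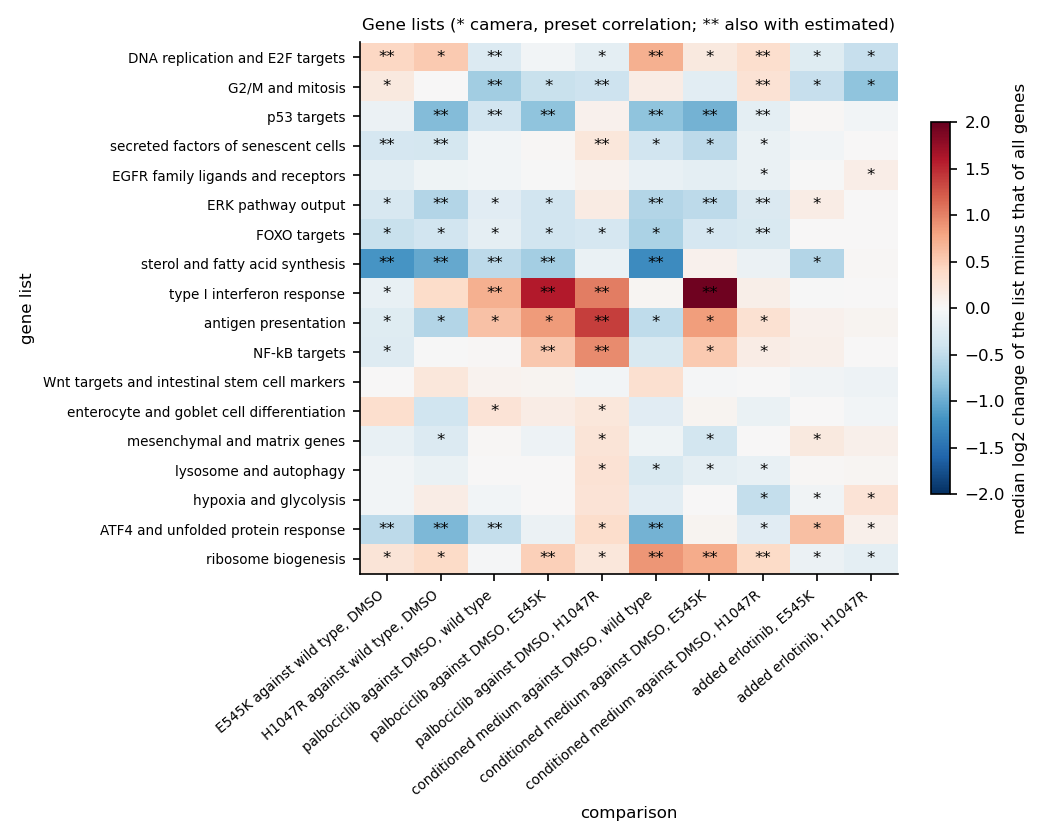
Median log2 change of each of 18 gene lists minus the median of all genes, as color, in the 10 comparisons of 2 groups, with 1 star for lists that passed camera with the preset correlation and 2 for those that also passed with an estimated one. Interferon genes had a median of 0.71, 1.59 and 1.02 under palbociclib in wild type, E545K and H1047R.

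Conditioned medium changes were shared in 3390 higher and 1419 lower genes by wild type and E545K (2121 and 583 expected), in 964 and 456 by wild type and H1047R (566 and 140 expected), and in 775 and 464 by the mutants (354 and 187 expected). With only the groups compared in the fit, shared calls fell from 1420 to 512 for wild type and H1047R and from 1239 to 459 for the mutants, and they rose to 2533 and 2186 after removal of the length and GC trend. Correlations across genes were 0.58, 0.54 and 0.44. The response of E545K differed from that of wild type in 1265 genes towards higher and 4672 towards lower values, and that of H1047R in 1313 and 5109. Shares higher of 21.3% and 20.4% became 46.2% and 48.1% after quantile normalization and 47.4% and 57.7% after median-centring. Both differences contain the DMSO libraries, so they are joined to what sets those of wild type and E545K apart. The log2 response of IFI44L, IFI6 and CCL20 lay higher in E545K than in wild type, with relative differences of 6.34, 5.58 and 4.94. That of VIM lay lower (-3.19). IFI44L fell in wild type from 7.5 to 1.2 FPKM and rose in E545K from 1.7 to 46.6. IFI6 fell in wild type from 53.3 to 19.8 and rose in E545K from 32.8 to 524.1. In H1047R, S100P and GADD45B differed by 3.06 and 3.00, and PPP1R10 and IL37 by -2.85 and -2.34. In each of these genes wild-type DMSO stood apart from the other groups compared. S100P was at 149.5 FPKM in wild-type DMSO, 9.8 in wild-type conditioned medium, and 11.6 and 5.3 in H1047R DMSO and conditioned medium. Sterol genes differed towards higher values in 24 of 30 in E545K (25 adjusted over the list alone; adjusted p 2.93e-23) and in 21 of 30 in H1047R, also adjusted over the list alone (adjusted p 2.27e-17). Within a genotype, palbociclib and conditioned medium share their DMSO libraries. They shared 2677 higher and 465 lower genes in wild type (1781 and 159 expected), 3254 and 1942 in E545K (1345 and 605 expected), and 603 and 329 in H1047R (213 and 149 expected). The expected numbers take the lists as independent. Shared calls in wild type fell from 3142 to 1962 after quantile normalization. Those in H1047R became 99 in place of 932 with only the groups compared in the fit, and 1696 after removal of the length and GC trend. Correlations across genes were 0.47, 0.84 and 0.42. Shared controls alone gave 0.50 in simulated unchanged groups. There all of the change is noise, so this correlation is no floor for groups that change and decides nothing here. Covariances were 0.095, 0.235 and 0.040, against 0.0075 to 0.0076 in the simulation, which gave 0.0 shared calls. The simulation drew independent noise with 1 spread per gene for all groups. It thus covers neither DMSO libraries set apart as a group, as in wild type and E545K, nor the larger spread of H1047R DMSO. A shared displaced control is therefore not excluded as a source of these covariances.

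Added erlotinib was compared with palbociclib alone in the second table, which asks what inhibition of the EGF receptor adds in the mutant lines. The combination lasted 48 hours per the labels, while the hours of palbociclib alone in this table are not stated. In E545K cells erlotinib went with lower sterol and mitotic genes and higher ATF4 genes, calls that passed camera with the preset correlation and not with an estimated one. S100P stood at 29.1 ± 2.58 against 7.04 ± 0.53 FPKM (log2 change 1.90, SE 0.17, adjusted p 0.000635), and DDIT4, ASNS and CHAC1 rose by 1.31, 1.29 and 1.28. INSIG1 (chromosome 7, 155297878 to 155310235 in GRCh38.p14) stood at 7.91 ± 0.38 against 29.9 ± 3.20 (-1.79, SE 0.08, adjusted p 5.65e-05). ALPG, FGFBP1, SCD, ARHGDIB and MTUS2 changed by -2.26, -2.18, -1.63, -1.55 and -1.49. Sterol genes were lower in 27 of 30, also adjusted over the list alone (median -0.58, adjusted p 4.08e-22; 0.119 with an estimated correlation), HMGCS1 by -1.10. Mitotic genes were lower in 38 of 42 (42 adjusted over the list alone; median -0.46, adjusted p 1.32e-24, 0.119 estimated), MKI67 by -0.68, ANLN by -0.77 and CCNA2 by -0.67. Replication genes were lower in 25 of 49 and higher in 1 (31 and 1 adjusted over the list alone; adjusted p 4.49e-11, 0.119 estimated). ATF4 genes were higher in 21 of 28 and lower in 1 (23 and 1 adjusted over the list alone; adjusted p 1.42e-19, 0.119 estimated). EGFR rose by 0.60 (SE 0.09) and CXCL1 changed by -0.86 (SE 0.14). The CCNA2 call was lost without E545K palbociclib replicate 1 or E545K combination replicate 2 (highest adjusted p 0.0526), and the CXCL1 call without either of these or combination replicate 1 (highest 0.0572). In all, 885 genes were higher and 1135 lower. The share higher, 43.8%, became 52.4% after quantile normalization and 37.1% on the TPM scale. Of 2 measured markers of non-epithelial cells 1 was lower here and 1 in H1047R, also adjusted over the list alone. Leaving out any of the 4 E545K libraries gave 512 to 694 genes in place of 2020, and a fit of the groups compared alone gave 3583. None of the 54 list tests of the second table passed with an estimated correlation, where the lowest adjusted p was 0.108. With 4 residual degrees of freedom that version has little power here, so it cannot decide whether these calls hold.

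In H1047R cells erlotinib went with lower mitotic and replication genes and higher hypoxia genes, again not past the threshold with an estimated correlation. MKI67 stood at 5.41 ± 0.17 against 11.0 ± 0.30 FPKM (log2 change -0.91, SE 0.05, adjusted p 0.000258), and TOP2A, CDKN3, PBK, CDC6 and RRM2 changed by -1.13, -1.21, -1.15, -0.91 and -0.89. Mitotic genes were lower in 41 of 42 (42 adjusted over the list alone; median -0.80, adjusted p 1.54e-42, 0.108 estimated) and replication genes in 43 of 49 (46 adjusted over the list alone; adjusted p 5.98e-26, 0.108 estimated). CDKN1A rose to 95.2 ± 0.52 from 68.1 ± 0.86 (0.48, SE 0.05, adjusted p 0.00109). HLA-DRB1, CD74, MYB and GNE changed by -1.27, -1.11, -1.25 and -1.59. KRT16, ANKRD37, NDRG1, MBOAT2 and SEMA7A rose by 1.49, 1.45, 1.26, 1.10 and 1.08. With no filter on low values GNE, KRT16, MBOAT2 and SEMA7A were not called (adjusted p 0.0741, 0.0847, 0.0642 and 0.0554). Without replicate 1 or 2 of H1047R palbociclib plus erlotinib, and with only the groups compared in the fit, GNE, KRT16, MBOAT2, NDRG1 and SEMA7A were not called. Their highest adjusted p were 0.154, 0.189, 0.128, 0.0904 and 0.126. CDC6 was not called without replicate 2 of the combination (0.0583) and, like RRM2, with only the groups compared in the fit (0.0659 and 0.0524). Hypoxia genes were higher in 12 of 26 (14 higher and 2 lower adjusted over the list alone; adjusted p 1.52e-08, 0.281 estimated), and ATF4 genes in 6 of 28 (10 adjusted over the list alone; adjusted p 4.41e-05, 0.281 estimated). The 2 H1047R palbociclib libraries differed from each other in members of the hypoxia list. NDRG1 stood at 14.0 ± 5.8 FPKM there and 33.7 ± 1.0 with erlotinib, and ANKRD37 at 2.2 ± 0.8 and 7.6 ± 1.1. Sterol genes did not pass (4 of 30 higher, 2 lower, adjusted over the list alone 6 and 2, adjusted p 0.228), except without H1047R palbociclib replicate 2 (0.000543), in a range up to 0.793. In all, 375 genes were higher and 792 lower. The share higher, 32.1%, became 45.9% after quantile normalization, 50.8% after median-centring and 20.5% on the TPM scale. The total of 1167 became 3795 without H1047R palbociclib replicate 1 and 323 and 201 without replicates 1 and 2 of H1047R palbociclib plus erlotinib. It was 115 with only the groups compared in the fit and 686 with no filter on low values.

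**Figure D5:**
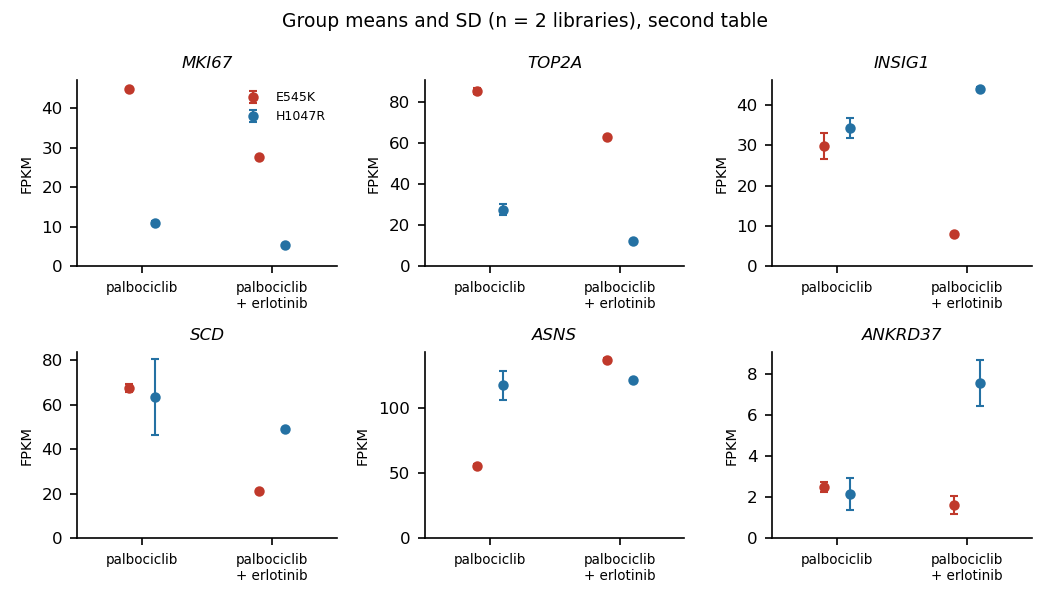
FPKM of 6 named genes in the second table under palbociclib with and without erlotinib, each point the mean of 2 libraries of a mutant line and each bar its SD. INSIG1 fell from 29.9 to 7.91 in E545K, and MKI67 from 11.0 to 5.41 in H1047R.

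The mutants shared 163 higher and 365 lower genes under added erlotinib (27 and 72 expected), with a correlation across genes of 0.44. These 528 shared calls became 92 with only the groups compared in the fit and 291 with no filter on low values. The response differed between them in 270 genes, 112 towards higher values in H1047R and 158 towards lower. The share of 41.5% became 55.3% after median-centring. Lists differed with the preset correlation of camera and not with an estimated one. Sterol genes differed in 17 of 30 towards higher values in H1047R (26 adjusted over the list alone; adjusted p 1.5e-30, 0.119 estimated), and ATF4 genes in 15 of 28 towards lower values, with 1 higher (20 and 2 adjusted over the list alone; adjusted p 2.67e-13, 0.119 estimated). INSIG1 differed by 2.14 (SE 0.12), ANKRD37 by 1.86 (SE 0.26), CAPN8 by -1.47 (SE 0.22) and ASNS by -1.24 (SE 0.09). The CAPN8 call was lost without any 1 library of E545K or of the H1047R combination, and the ANKRD37 call without any 1 of these except E545K combination replicate 2, with highest adjusted p of 0.0998 and 0.0795. Both were also lost with no filter on low values. Mitotic genes differed in 12 of 42 towards lower values (31 adjusted over the list alone; adjusted p 1.19e-18, 0.119 estimated) and hypoxia genes in 8 of 26 towards higher values (19 higher and 1 lower adjusted over the list alone; adjusted p 5.78e-15, 0.175 estimated). The spread of hypoxia genes between the H1047R palbociclib libraries limits the hypoxia result here too. The total of 270 became 112 with no filter on low values and 141 with a replicate block. Each of the 8 libraries moved this total. It was 2079 and 917 without replicates 1 and 2 of H1047R palbociclib, and 34 to 48 without any 1 of the other libraries.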

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

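The tests of a wrong label, of a few abundant genes, of a shared culture or harvest state, of another E545K culture and of medium alone were chosen after the results were seen. The lists below are those that passed camera with both the preset and the estimated correlation.

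Responses of the 2 mutant lines were tested for a difference from wild type, or from each other. Differences from wild type contain the DMSO libraries of both lines. They cannot be separated here from what sets the DMSO libraries of wild type and E545K apart. Under palbociclib 3234 genes differed between E545K and wild type. Log2 differences were 4.05 for CXCL2, 3.69 for CCL20, -2.67 for ALPG and -2.47 for KRT14. List medians relative to all genes were 0.76 for interferon genes, 0.46 for ribosome biogenesis, 0.40 for NF-kB targets and -0.44 for p53 targets. Between H1047R and wild type 2845 genes differed. Relative differences were 2.50 for IFI27, 2.48 for NOS2, 2.22 for CXCL8, -0.49 for PIK3CA and -1.71 for HOXB4. The PIK3CA call was lost without H1047R DMSO replicate 2 (adjusted p 0.0512), without wild-type palbociclib replicate 1 (0.0544) and with only the groups compared in the fit (0.0936), in a range from 0.000353 to 0.0936. List medians were 0.80 for NF-kB targets, 0.68 for antigen presentation, 0.58 for ATF4 genes, 0.55 for secreted factors of senescent cells and 0.38 for interferon genes. They were 0.36 for each of p53 targets, ERK output and sterol genes. That total became 1663, 1291, 1268, 1671 and 1428 without wild-type DMSO replicate 1 or 2, wild-type palbociclib replicate 1 or 2, or H1047R DMSO replicate 2, and 5562 without H1047R palbociclib replicate 1.

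In conditioned medium 5937 genes differed between E545K and wild type. Relative differences were 6.34 for IFI44L, 5.58 for IFI6, 4.94 for CCL20, 1.01 for PIK3CA and -3.19 for VIM. List medians were 1.75 for interferon genes, 1.35 for sterol genes, 1.01 for antigen presentation, 0.85 for ATF4 genes, 0.68 for NF-kB targets and -0.54 for replication genes. Between H1047R and wild type 6422 genes differed, with S100P at 3.06, GADD45B at 3.00, PPP1R10 at -2.85 and IL37 at -2.34. List medians were 1.17 for sterol genes, 0.68 for p53 targets and 0.65 for ATF4 genes. In the named genes wild-type DMSO alone stood apart. PPP1R10 was at 2.6 FPKM there, 32.5 in wild-type conditioned medium, and 30.1 and 32.2 in H1047R DMSO and conditioned medium. Mean profiles of wild type and H1047R correlated at 0.990 in conditioned medium and at 0.945 in DMSO. Under added erlotinib 270 genes differed between H1047R and E545K, with INSIG1 at 2.14, ANKRD37 at 1.86, CAPN8 at -1.47 and ASNS at -1.24. The ANKRD37 and CAPN8 calls were lost in 6 and 7 of 16 alternatives, with adjusted p up to 0.0795 and 0.0998: CAPN8 without any 1 library of E545K or of the H1047R combination, and ANKRD37 without any 1 of these except E545K combination replicate 2. Leaving out H1047R palbociclib replicate 1 or 2 gave 2079 or 917 genes, and leaving out any 1 of the other 6 libraries gave 34 to 48.

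Wild type in conditioned medium had 8883 changed genes and moved towards the mutant libraries on the first component. A wrong label was tested with genes seen in wild type alone: a first criterion left 2 genes, both seen in wild type in conditioned medium, and a looser one set afterwards left 7, of which 6 (85.7%) were seen there and 0 in either mutant in conditioned medium, which argues against it. Quantile normalization left 8409 changed genes and removal of the length and GC trend left 9503, which argues against abundant genes or such a trend as the whole cause. The change correlated at 0.64 across genes with the palbociclib change of E545K, which shares no library with it. It correlated at 0.54 with the conditioned-medium change of H1047R. The palbociclib change of E545K correlated at 0.53 and 0.52 with that of wild type and H1047R. A state of culture or harvest shared by some libraries may contribute to both changes. As the source of the medium is not stated, a treatment in common is not excluded. A biological effect of the medium stays open too, as do density, spent medium and harvest time, which the labels do not resolve.

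E545K libraries in conditioned medium lay apart from E545K in DMSO and palbociclib in 83 genes, VIM among them. In 53 of these (63.9%, exact 95% confidence interval 52.6 to 74.1) E545K palbociclib libraries of the second table lay nearer to the conditioned-medium level than to the first table's palbociclib level. Their median position was 0.67 of the way (bootstrap 95% interval 0.53 to 0.73). The same measure in H1047R gave 5 of 11 genes (45.5%, 16.7 to 76.6) and 0.50 of the way (-0.18 to 0.56), and the shares of the lines did not differ detectably (two-sided Fisher's exact p 0.324), a comparison added after the values were seen. The intervals and the Fisher test take genes as independent, so they do not measure the spread between libraries. Genes were chosen by a large distance between conditioned medium and palbociclib in the first table. That choice alone can place new palbociclib libraries nearer to conditioned medium. Levels were compared between tables without an offset. With so few H1047R genes, an E545K culture or subline shared with the second table and the medium alone cannot be told apart here. Other differences between the tables were not tested.

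The palbociclib change of H1047R followed GC content at a rank correlation of 0.36 across genes and length at -0.25. These became 0.14 and -0.06 without H1047R palbociclib replicate 2, and 0.45 and -0.35 without replicate 1. Of 101 genes in the interferon, antigen presentation and mitosis lists, 87 were called in the direction of their list. After removal of the length and GC trend 91 were called, and without replicate 2 it was 88, which argues against the trend or that library as the whole source of these calls. The origin of the trend was not tested.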

How the results depend on the processing

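Median-centring, removal of the length and GC trend, and all alternatives for shared calls were chosen after seeing the data. Of 235 gene results 215, and of 270 list results 159, kept their side of the threshold under every alternative run. Their direction was compared only where the main fit or the alternative made a call. An estimated correlation, with the fewer degrees of freedom that go with it, took 88 list results out of the called set.

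Unless a value or the construction of an alternative shows it, the cause was not tested. With only the groups compared in the fit, changed genes numbered 480 for palbociclib in H1047R (4951 in the full fit), 288 for its difference from wild type (2845), 605 for conditioned medium in H1047R (1844), and 3583 and 115 for added erlotinib in E545K and H1047R (2020 and 1167), while the other 10 counts stayed within 1.5 times. The falls were in H1047R comparisons, where residual SD was largest (0.119 in DMSO and 0.159 in palbociclib against 0.067 to 0.081 in other groups, and 0.117 against 0.062 to 0.068 in the second table), and the full fit pools that spread with that of the other groups. Shared calls were 402 for palbociclib in both mutants, 396 in wild type and H1047R, 459 for conditioned medium in both mutants, 512 in wild type and H1047R, 99 for palbociclib and conditioned medium in H1047R, and 92 for added erlotinib.

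With no filter on low values, added erlotinib gave 686 genes in H1047R, 112 for the difference between mutants (270) and 291 shared calls (528). A replicate block gave 141 for that difference. Quantile normalization gave 1851 for the palbociclib difference of H1047R and 1962 shared calls of palbociclib and conditioned medium in wild type (3142). Without the length and GC trend, conditioned medium in H1047R gave 3315 genes, and shared calls were 2186 with E545K, 2533 with wild type and 1696 with palbociclib. PIK3CA reversed after quantile normalization in wild type in conditioned medium (log2 change -0.28, from 0.14) and in H1047R against wild type in DMSO (-0.13, from 0.28; -0.07 after median-centring).

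When 1 library was left out, the lone library was assumed to vary like the other groups. Counts ranged from 2616 to 2725 for palbociclib in wild type, below 4287 without any 1 of the 4 libraries. For palbociclib in H1047R they ranged from 2732 (without H1047R DMSO replicate 2) to 6780, and for its difference from wild type from 1268 (without wild-type palbociclib replicate 1) to 5562 (without H1047R palbociclib replicate 1). Conditioned medium in H1047R gave 686 (without either of its libraries) to 1518. Added erlotinib gave 512 to 694 in E545K, 201 (without H1047R combination replicate 2) to 3795 (without H1047R palbociclib replicate 1) in H1047R, and 34 to 2079 for the difference, again highest without H1047R palbociclib replicate 1. The hypoxia list in the palbociclib difference of H1047R, at an adjusted p of 0.0101, ranged from 4.69e-09 to 0.486 and reversed without H1047R DMSO replicate 2. Its call was also lost with an estimated correlation (0.605), after quantile normalization (0.39) and after median-centring (0.0527), so its alternatives ranged from 4.69e-09 to 0.605. Unknown read depth limits what can be said of genes near 0 FPKM.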

Other observations

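The genes in this part were chosen after their values were seen. Several genes lower in both mutant lines than in wild type lie close together. On chromosome 11 (GRCh38.p14), HBG2 spans 5253188 to 5254781, HBE1 5268345 to 5269945, OR51B4 5301014 to 5301946 and OR51B5 5340318 to 5505652. HBE1 stood at 148, 172 and 87.7 FPKM in wild type in DMSO, palbociclib and conditioned medium, at 1.56 to 6.46 in E545K and at 0.48 to 0.86 in H1047R. OR51B5 stood at 13.6, 17.7 and 11.8 FPKM in wild type in DMSO, palbociclib and conditioned medium, and at 0.08 to 0.53 in the mutant groups. MAGEA6 stood at 8.71, 11.4 and 20.4 in wild type and at 0.07 or less in the mutant groups, and its near-identical copy MAGEA3 at 2.21, 3.38 and 4.72. Reads shared by such copies leave their split uncertain.

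H1047R was also compared with E545K under palbociclib in each table, over 12314 genes. The differences correlated across genes at 0.37 (Pearson) and 0.16 (Spearman). Of 1337 genes called in both tables, 1069 (80.0%) had the same direction, where 555 were expected from independent lists. Hours of palbociclib are stated for the first table alone.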
